A study of Homo sapiens with 2 samples.

How the data were processed

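The labels describe 2 dual-colour arrays of HepG2 RNA, 1 for each of 2 independent experiments. Per the labels, total RNA was amplified to amino allyl RNA and coupled to dyes by the protocol of the array's maker. RNA of infected cells without cytokines carried Cy5 and RNA of cytokine-treated infected cells carried Cy3 on both arrays, so the number of dye-swapped arrays is 0. The authors deposited 1 log ratio per probe and array, read here as log2, with a median of exactly 0 on each array. The scanner, the background correction, the normalization and the rule by which values were set to null are not given in the sources used here. Base and direction of the deposited log ratios are not stated. The base was read as 2 from the range of the values, and the direction as cytokine-treated over untreated from the order of the pair in the sample titles and the design text. No channel intensities were used here, so it is unknown how far above background a value lies, and the number of arrays limits the precision. Null values made up 25.2% of replicate 1 and 23.3% of replicate 2. A probe without intensities can give a large ratio from little signal, and centring hides any shift shared by all genes.

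Gene symbols came from the platform annotation, in which 13395 of 24267 probes had 1 symbol, 0 had several and 10872 were unnamed here. Symbols were checked against the RefSeq genes of assembly GRCh38.p14. Of the named probes 10822 carried a current symbol, 2446 were updated through a synonym and 127 kept the given name. No coordinates are given, because no genome build is named for the array. Probes with a value on both arrays were tested at probe level. For genes, the log2 ratios of all named probes were averaged. Of 452 genes with several probes, 214 had probes whose mean ratios differed in sign.

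The 2 arrays formed 1 group, and their mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3, using lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each probe has 1 residual degree of freedom, to which eBayes added a prior of 3.49 at probe level and 3.57 at gene level. Errors are SDs of the 2 arrays. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 29 lists, and with an estimated correlation, which rests on 1 residual degree of freedom. The rotation test fry was a further alternative. The test was tried on simulated data with the spread of these arrays. In these data each gene was drawn independently of the others. Camera called 1 list in 50 simulated runs of 29 lists without a change. This gives no rate of false calls for lists whose genes vary together. A list shifted by 0.5 was called in 50 of 50 runs at the preset correlation and in 0 of 50 with an estimated correlation, so the estimated correlation cannot pass such a list with 2 arrays. Random lists numbered 10000, and intervals are 95% bootstrap intervals over genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for these and for the plots.

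The groups, the tests, the 29 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, in each direction, the 12 genes with the largest value of the smaller of the 2 absolute log2 ratios among genes of the same sign on both arrays. Genes past limma's threshold come first, and since 0 passed, all are filled by rank. From each list up to 2 members were taken by the same rank, and from the receptors IL17RA, IL17RC, IL22RA1 and IL10RB. A list's members are also named where they passed adjusted over the list alone, were left out or were null, and these, like others outside the rule, were chosen after their values were seen. Alternatives were centring, scaling and quantile normalization of the arrays, robust or no moderation, a test against a fold change of 1.2, other fold thresholds, other treatments of probes, each array alone, and other list tests.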

Results

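Gene expression was compared by dual-colour microarray in HepG2, a human hepatocellular carcinoma line, infected with Listeria monocytogenes, a bacterium that multiplies inside host cells, hepatocytes among them. Cells of one arm were given IL-17A at 50 ng/ml together with IL-22 at 10 ng/ml ahead of infection at a multiplicity of infection of 10, and cells of the reference arm were infected at the same multiplicity without cytokines. IL-17A and IL-22 are cytokines of T helper 17 cells and of innate lymphoid cells. The RNAs of both arms were hybridised to the same array in each of 2 independent experiments, so every value is a ratio within 1 experiment and n = 2 throughout. Replicate 1 carried values for 18158 of 24267 probes and replicate 2 for 18602, with 17092 probes on both arrays. Of these, 9675 had a gene symbol, which gave 9165 genes. The SD of the log2 ratios over probes was 0.42 on replicate 1 and 0.43 on replicate 2. Ratios are given as cytokine-treated over untreated, a likely direction that rests on the order in which the sample titles and the design text name the pair. The log base was read as 2, and a reversed direction would turn every sign given here.

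The main comparison asked which transcripts of infected HepG2 cells differ when IL-17A and IL-22 precede the infection. LBP, which encodes the lipopolysaccharide-binding protein secreted by hepatocytes, led the genes with higher ratios, ranked by the smaller of their ratios on the 2 arrays, at 6.44-fold, with a mean log2 ratio of 2.69 ± 0.31 (SD, n = 2). SAA1, the gene of the acute-phase apolipoprotein serum amyloid A, was next by that rank at 3.64-fold, 1.86 ± 0.35 (SD, n = 2). PTGES, an enzyme of prostaglandin E2 synthesis, had a ratio of 1.53 ± 0.28, and HPR, a close paralog of the haptoglobin gene that a probe may not separate from it, 1.33 ± 0.06. The lipid transporter gene ABCA8 (2.78-fold) and GUCY1B2 (2.70-fold) were in the same set. The other 6 of the 12 genes named on this side are best known from other tissues. They were the neuronal filament genes NEFH (3.18-fold) and INA (2.88-fold), the neurotrophic factor receptor gene GFRA3 (3.20-fold), the pluripotency factor gene NANOG (2.84-fold) and the olfactory receptor genes OR5AS1 (2.82-fold) and OR1S1 (2.64-fold).

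On the lower side, the apolipoprotein gene APOA2, a major protein of high-density lipoprotein, had log2 ratios of -1.20 and -1.95 on the 2 arrays. COL25A1, a transmembrane collagen gene, stood at -1.30 ± 0.03, and NTRK3, a neurotrophin receptor gene, at -1.33 ± 0.16 (SD, n = 2). The remaining 9 lay between 1.85-fold and 2.34-fold lower: ZNF653, EHMT1, a histone methyltransferase gene, LRRC14, ACRV1, NALF2, RNF44, BCAT2, an enzyme gene of branched-chain amino acid breakdown, FSTL3 and CCDC170. None of these 24 genes passed limma's test after Benjamini-Hochberg adjustment, and LBP had an adjusted p of 0.271. By limma 0 of 17092 probes passed, with a smallest adjusted p of 0.274. An unadjusted p under 0.05 was reached by 1718 probes, 758 higher and 960 lower, where chance alone would give 855. With probes of 1 array included there were 2900, 1779 higher and 1121 lower, but the added probes have 0 residual degrees of freedom and take their spread wholly from limma's prior. Limma's treat against a fold change of 1.2 gave 809. At gene level limma again passed 0 of 9165, with 877 at an unadjusted p under 0.05. The test without moderation passed 28 probes, which are the 28 whose values are identical on both arrays to 3 decimals. In data simulated with the spread of these arrays and with 200 genes changed at once, limma recovered 0% of them at a true log2 ratio of 1. At a ratio of 2 it recovered 98%. The adjusted p of a gene depends on how many others change, and fewer changed genes were not simulated. The 98% is therefore no measure of power for a few genes, and LBP, at a mean log2 ratio of 2.69, did not pass. Both arrays carried the treated RNA in Cy3 and the untreated RNA in Cy5, so a dye effect of a probe cannot be separated from the treatment.

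**Figure D1:**
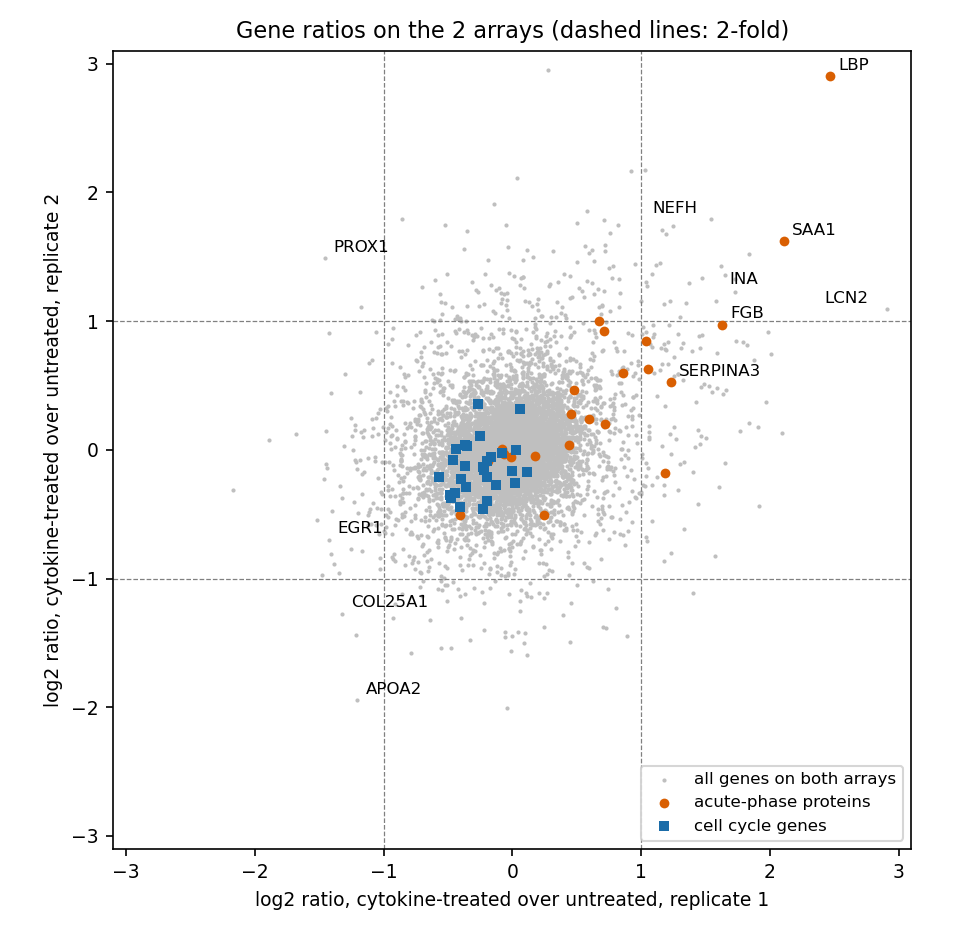
Each point is a gene, placed by its log2 ratio (cytokine-treated over untreated) on replicate 1 and on replicate 2, with acute-phase protein genes in orange and cell cycle genes in blue. LBP and SAA1 lie at the upper right on both arrays, 25 genes lie past the dashed 2-fold lines in the upper right corner and 3 in the lower left.

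Without use of the variance, 25 genes were 2-fold or more higher on both arrays, and 3 were 2-fold or more lower. The higher set held LBP, SAA1, LCN2, PLA2G2A and CEBPD, the 5 that belong to gene lists fixed before the data were examined. It also held, named after their values were seen, the peptidylarginine deiminase gene PADI2 (1.37 ± 0.30), the serine protease gene PRSS22 (1.23 ± 0.20) and the apolipoprotein L gene APOL2 (1.19 ± 0.05). The lower set was APOA2, COL25A1 and NTRK3. Independent arrays with the same numbers of 2-fold genes would give 1.92 higher and 0.52 lower. Another 3 genes passed 2-fold in opposite directions, against 2.03 from independent arrays: the hepatocyte transcription factor gene PROX1 (-1.46 and 1.49), DNASE1L3 (-1.18 and 1.11) and PHKA2 (1.40 and -1.11). At 1.5-fold the counts were 124 higher, 64 lower and 59 opposite, against 18.6, 15.4 and 34.8 from independent arrays, and at 3-fold LBP and SAA1 alone were higher with 0 lower. On one array alone, 123 or 143 genes were 2-fold higher and 76 or 63 lower.

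Across the 9165 genes the log2 ratios of the 2 experiments had a Pearson correlation of 0.244 and a Spearman correlation of 0.219, and 58.2% of genes had the same sign on both arrays. The 641 genes with an absolute mean log2 ratio of at least 0.5 had a Pearson correlation of 0.621 and the same sign in 92.0%, a set chosen on the mean of the same values. Markers of cell types absent from HepG2 cultures, namely blood, stromal, endothelial, neuronal and germ cells, shared their sign in 50% of 26 genes, with a Pearson correlation of 0.345 and a Spearman correlation of 0.103. These correlations are across genes, which are not independent replicates, and a dye effect shared by both arrays also enters them.

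The 29 gene lists asked which groups of genes known from liver, cytokine and infection biology moved together. Acute-phase proteins, the plasma proteins that hepatocytes secrete in inflammation, had the highest mean log2 ratio over both arrays, 0.57 over 22 measured genes, with means of 0.70 on replicate 1 and 0.45 on replicate 2, where antimicrobial proteins were higher at 0.55. On both arrays 14 members were higher and 4 lower, and 4 differed in sign. By limma's camera with a preset correlation of 0.01 the list's adjusted p was 2.15e-07. With an estimated correlation the adjusted p was 0.773. Adjusted over the list alone 11 members passed limma's test, and over all genes 0. LBP and SAA1 were among the 11. The others were CP, the copper-carrying plasma ferroxidase gene, at 0.82 ± 0.15, and, named after their values were seen, the 3 fibrinogen chain genes FGB (1.30 ± 0.46), FGG (0.84 ± 0.30) and FGA (0.73 ± 0.19), LRG1, HAMP, SERPINA3, FGL1 and A2M. HAMP, the gene of the iron-regulating hormone hepcidin, was at 0.84 ± 0.24, and A2M, a protease inhibitor gene, was the lower one at -0.46 ± 0.07. The 2 probes of A2M had mean ratios of -0.66 and -0.25, and on replicate 1 they stood at -0.81 and -0.006. CRP was null on both arrays, and HP and SAA2 had no probe named here.

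**Figure D2:**
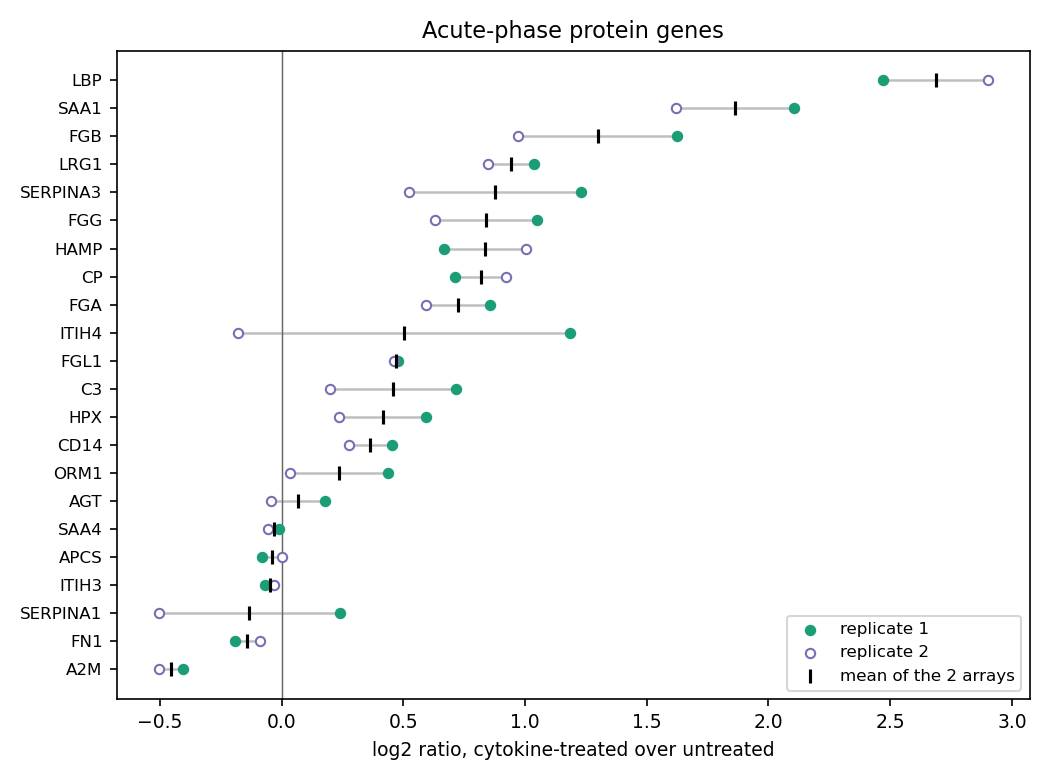
Log2 ratios (cytokine-treated over untreated) of the 22 measured acute-phase protein genes, with replicate 1 filled, replicate 2 open and their mean as a black bar. LBP and SAA1 stand above 1.5 on both arrays, and A2M stands lowest at -0.46.

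Antimicrobial proteins had a mean log2 ratio of 0.48 over 10 measured genes of 32 listed, with 6 higher and 1 lower on both arrays. Of the unmeasured members, 9 had no probe named here, 7 were null on both arrays and 6 on 1 array. LCN2, whose product lipocalin-2 binds bacterial siderophores, was 4.01-fold higher but differed between the arrays, at 2.91 and 1.09. PLA2G2A, a secreted phospholipase gene active against Gram-positive bacteria, was at 1.16 ± 0.16 (SD, n = 2). Camera gave an adjusted p of 0.0157. The adjusted p was 0.773 with an estimated correlation and 0.0605 without LCN2. Adjusted over the list alone LCN2, PLA2G2A and HAMP passed limma's test, and over all genes 0 did.

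Interferon-stimulated genes had a mean log2 ratio of 0.15 over 29 measured genes, with 16 higher and 2 lower on both arrays. IFITM3 and IFITM2, genes of membrane proteins that restrict virus entry, were at 0.60 ± 0.10 and 0.48 ± 0.13 (SD, n = 2). Camera gave an adjusted p of 0.0157, and with an estimated correlation the adjusted p was 0.773. Autophagy and lysosome genes had a mean of 0.13 over 28 genes, 13 higher and 2 lower on both arrays. TFEB, a transcription factor gene that drives lysosome genes, was at 0.95 ± 0.08, and CTSS, a lysosomal protease gene, at 0.64 ± 0.28. This list had a camera adjusted p of 0.0168. The adjusted p was 0.773 with an estimated correlation and 0.0565 without TFEB. Adjusted over each list alone, limma passed 0 interferon-stimulated genes, with 5 at an unadjusted p under 0.05, and 1 autophagy and lysosome gene, TFEB, and over all genes 0 of either list.

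Cell cycle genes had a mean log2 ratio of -0.20 over 28 measured genes, with means of -0.25 and -0.14 on the 2 arrays. On both arrays 19 were lower and 2 higher. The mitotic kinase gene AURKB was at -0.43 ± 0.03 and the cyclin gene CCNA2 at -0.43 ± 0.07 (SD, n = 2). All 6 measured subunit genes of the replicative helicase, MCM2 to MCM7, were lower on both arrays, from -0.42 to -0.19, a group chosen after its values were seen. Camera gave an adjusted p of 0.000262, and with an estimated correlation the adjusted p was 0.773. Ribosomal proteins had a mean of -0.16 over 20 genes, -0.10 on replicate 1 and -0.22 on replicate 2. On both arrays 12 were lower and 1 higher, with RPS2 at -0.73 ± 0.09 and RPL37 at -0.46 ± 0.06. Their adjusted p was 0.0157 by camera. It was 0.773 with an estimated correlation and 0.0558 without RPS2. Immediate early genes, which code for transcription factors and phosphatases induced within minutes of a stimulus, had a mean of -0.19 over 28 genes, 15 lower and 4 higher on both arrays. This mean rested on replicate 1, at -0.36 against -0.02 on replicate 2. EGR1 was at -1.06 ± 0.51, and DUSP4 went the other way at 0.90 ± 0.64. The camera adjusted p was 0.0157, and with an estimated correlation the adjusted p was 0.786. Adjusted over each list alone, as over all genes, limma passed 0 members of these 3 lists, where each had 4 at an unadjusted p under 0.05.

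Hepatocyte identity genes had a mean log2 ratio of -0.18 over 25 measured genes, with 11 lower and 5 higher on both arrays. The lower ones included APOA2 and, named after their values were seen, the apolipoprotein genes APOC3 (-0.74 ± 0.32) and APOA1 (-0.55 ± 0.15), the transthyretin gene TTR (-0.63 ± 0.31) and the albumin gene ALB (-0.36 ± 0.33). FABP1, the liver fatty acid-binding protein gene, went the other way at 0.94 ± 0.38. Camera gave an adjusted p of 0.0293. The adjusted p was 0.773 with an estimated correlation and 0.0860 without APOA2. Adjusted over the list alone APOA2 passed limma's test, and over all genes 0 did. Drug and bile acid metabolism genes had a mean of -0.12 over 24 genes, with BAAT, an enzyme gene of bile acid conjugation, at -0.62 ± 0.09 and the nuclear receptor gene NR1I3 at -0.47 ± 0.02. That list did not pass, at an adjusted p of 0.0509.

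Genes known to respond to IL-17A had a mean log2 ratio of 0.35 over 13 measured members, with 7 higher and 3 lower on both arrays. The lower ones, named after their values were seen, were LIF, TNFAIP3 and CXCL3. The list did not pass camera, at an adjusted p of 0.0622, and 0.215 without LCN2. Adjusted over the list alone 4 members passed limma's test, namely LCN2, the NF-kB cofactor gene NFKBIZ at 0.76 ± 0.16, the neutrophil chemokine gene CXCL2 at 0.96 ± 0.48 and, outside the naming rule, MMP3. Values were null on both arrays for 11 members, among them CXCL1, CCL2 and IL6, and the mean ratios of the 3 probes of CXCL8 differed in sign, at 0.52, -0.23 and -0.36. Genes known to respond to IL-22 and STAT3 went both ways, with 7 higher and 8 lower on both of the arrays among 20, and an adjusted p of 0.895. CEBPD, a transcription factor gene of the acute-phase response, was at 1.17 ± 0.19 and was the 1 member that passed limma's test adjusted over the list alone, while the survival genes BIRC5 and BCL2L1 were at -0.60 ± 0.11 and -0.30 ± 0.01. Named after their values were seen, SOCS1 was at 0.58 ± 0.13 and NNMT at 1.07 ± 0.85. The list shares no member with the acute-phase list, so its result does not cover those genes. The list's mean was 0.08, 0.02 and 0.14 on the 2 arrays, and its median was -0.02, with -0.21 on replicate 1, at the 0.36th percentile of random lists, and 0.03 on replicate 2, at the 70.1th. Among the receptors, IL17RC was at -0.10 ± 0.04, IL22RA1 at -0.17 ± 0.07 and IL10RB at 0.15 ± 0.06. IL17RA differed in sign between the arrays, at -0.61 and 0.05. The list of receptors and signalling genes had an adjusted p of 0.313.

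Of the lists on bacterial sensing and plasma defence, pattern recognition had an adjusted p of 0.149. In it LY96, the gene of the TLR4 co-receptor MD-2, was at 1.03 ± 0.09 and TLR4 itself at -0.52 ± 0.01, and LY96 passed limma's test adjusted over the list alone. Complement and coagulation genes had an adjusted p of 0.176, with the mannose-binding lectin gene MBL2 at 0.87 ± 0.26 and PROS1, the gene of protein S, at 0.58 ± 0.10. Iron metabolism had the same adjusted p of 0.176, and 5 of its 23 members passed limma's test adjusted over the list alone, with LCN2, CP and HAMP higher. The lower ones, named after their values were seen, were FTL, the ferritin light chain gene, at -0.86 ± 0.23, and SMAD7 at -0.81 ± 0.43. Chemokines had an adjusted p of 0.959, with CCL22 at 1.03 ± 0.27 as the 1 member that passed adjusted over the list alone. NF-kB target genes had an adjusted p of 0.381, with the mitochondrial superoxide dismutase gene SOD2 at 0.81 ± 0.04 and TNFAIP8 at 0.47 ± 0.19. The list of Listeria entry and spread, the host genes through which the bacterium invades and moves between cells, had an adjusted p of 0.272, with CBLB at -0.37 ± 0.26 and DAB2 at -0.26 ± 0.11.

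The remaining lists did not pass camera either. Their adjusted p-values were 0.176 for fatty acid and lipid metabolism, with PPARGC1A at -0.49 ± 0.30, and 0.452 for commonly used reference genes, with RPLP0 at -0.42 ± 0.08. They were 0.7 for metallothioneins, 0.747 for glycolysis and hypoxia genes, 0.772 for cholesterol synthesis, and 0.959 for apoptosis regulators, for oxidative stress genes and for the unfolded protein and integrated stress responses. Markers of absent cell types did not pass as lists, at 0.474 for neuron and germ cells, 0.656 for blood cells and 0.747 for stromal and endothelial cells. Single markers still reached high ratios, with the lymphatic endothelial gene LYVE1 at 1.29 ± 0.66 and the T cell gene CD3G at 0.83 ± 0.67. LYVE1, a marker of a cell type absent here, passed limma's test adjusted over its list alone, as some of the liver genes did over theirs. For chemokines, blood cell markers, oxidative stress genes and the stress response list, mean and median differed in sign.

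**Figure D3:**
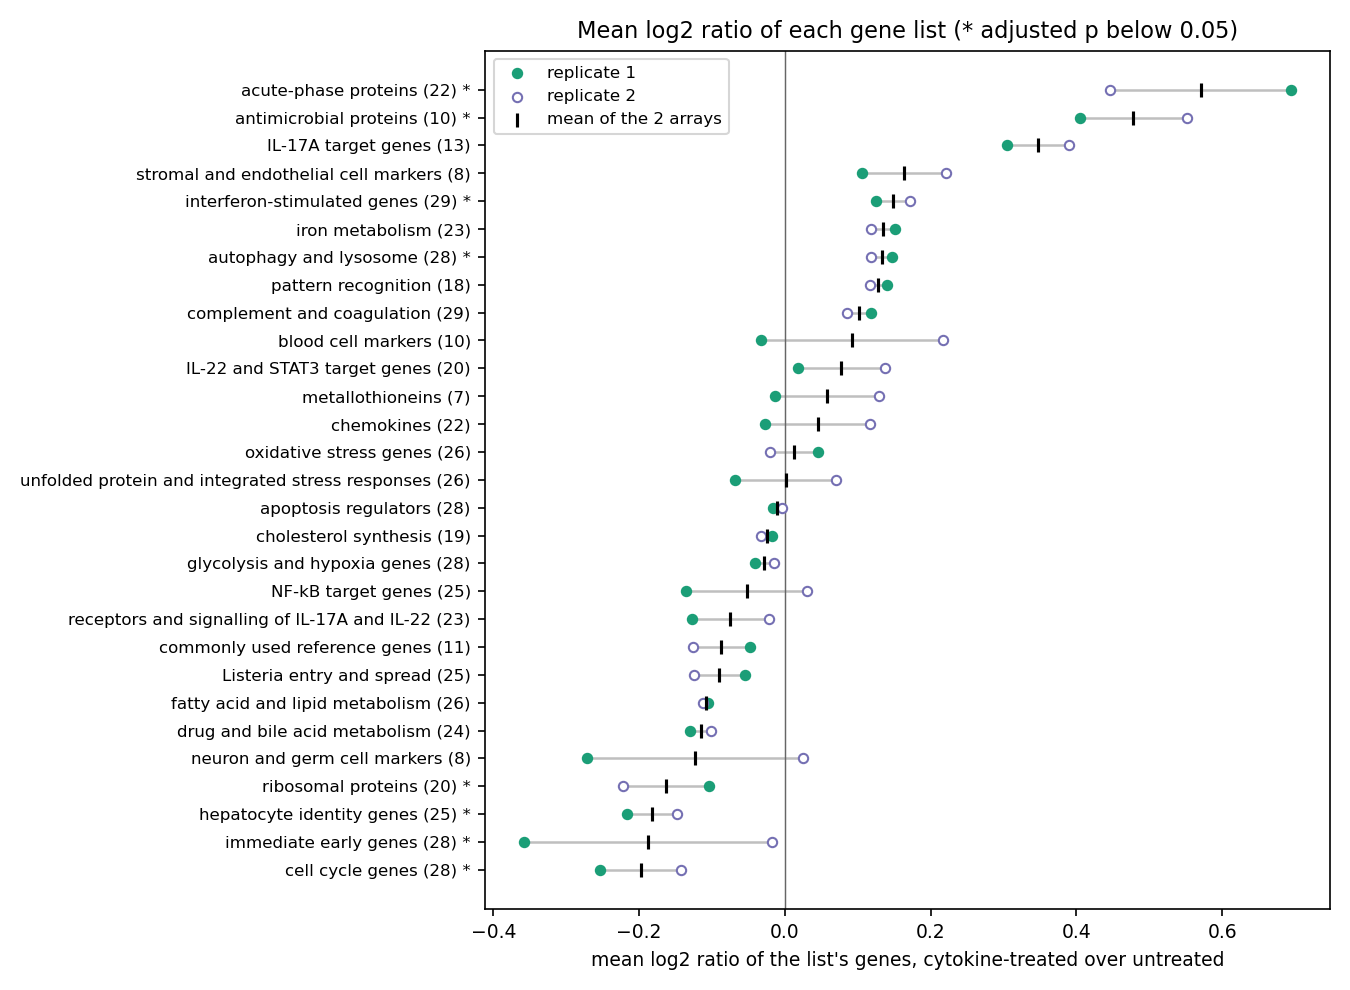
Mean log2 ratio (cytokine-treated over untreated) of each of the 29 gene lists, with the number of measured genes in parentheses, replicate 1 filled, replicate 2 open and the mean as a black bar. An asterisk marks the 8 lists with a camera adjusted p under 0.05 at the preset correlation, and none of these passed with an estimated correlation.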

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

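The scaled and quantile-normalized means of the lists, each array's list means and the turned sign were chosen after the data were seen, and the other alternatives before. The probe count by limma stayed at 0 with centring, scaling, quantile normalization, robust moderation, a fold change of 1.2, named probes, gene level and probes of 1 array included, and was 28 without moderation, where identical values on both arrays give a spread of 0. Its count at an unadjusted p under 0.05, 1718 with 758 higher and 960 lower, became 2900 with 1779 higher and 1121 lower when probes of 1 array were included, whose spread is limma's prior alone. Genes 2-fold higher on both arrays numbered 25, against 124 at 1.5-fold, 2 at 3-fold, 3 with the sign turned and 123 to 143 on a single array. Those lower numbered 3, against 64, 0, 25 and 63 to 76, and 5 with scaled arrays. The fold thresholds and the use of 1 array change these counts by construction. The Pearson correlation of the arrays was 0.621 in genes with an absolute mean of at least 0.5 and 0.345 in markers of absent cell types, and the shares with the same sign were 92.0% and 50%. Lists that passed numbered 8, against 0 with an estimated correlation, 0 by fry and 5 without each list's largest member, the 5 being 4 of the 8 and drug and bile acid metabolism. With an estimated correlation the adjusted p was 0.773 for 7 of the 8 and 0.786 for immediate early genes. By fry it was 0.430 for acute-phase proteins, 0.432 for antimicrobial, cell cycle, hepatocyte identity and ribosomal genes, 0.427 for autophagy and lysosome, 0.648 for immediate early and 0.284 for interferon-stimulated genes. On ranks it was 0.0780 for antimicrobial and 0.0591 for hepatocyte identity genes. Without the largest member it was 0.0605 for antimicrobial proteins, 0.0565 for autophagy and lysosome, 0.0860 for hepatocyte identity and 0.0558 for ribosomal proteins. By the median among random lists it was 0.0818 for autophagy and lysosome and 0.0947 for hepatocyte identity and for ribosomal proteins. Over these alternatives the adjusted p ranged from 3.26e-07 to 0.773 for acute-phase proteins and from 0.000219 to 0.773 for cell cycle genes. In the other direction, lists that had not passed did so by the median among random lists, at 0.0377 for IL-17A targets, 0.0389 for iron metabolism and 0.0406 for pattern recognition, and drug and bile acid metabolism passed at 0.0483 with centred arrays and 0.0385 without its largest member. The cause was not tested for any change of a list's call other than the loss with an estimated correlation, which has 1 residual degree of freedom. Camera on the ranks of a single array was not run, because the genes of 1 array are not replicates. No further pairing was possible, because each array already pairs the RNAs of 1 experiment. Signal over background is unknown, so which ratios rest on dim probes cannot be read from these values.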

Other observations

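The repeated noise test of genes from absent cell types, the liver-wide and dye-swap tests of the acute-phase list, the test of the cell cycle list against ribosomal proteins, the test of symbol families and the median of probes with a value on 1 array were chosen only after the results were seen, and the bars of the repeated noise test and of the liver-wide test were set again after their values were known. Mitosis genes outside the fixed cell cycle list also lay lower. Of 61 such genes listed before their values were seen, 44 were measured, with a median log2 ratio of -0.12, and 20 were lower on both arrays against 6 higher. Of 59 families of genes sharing a symbol stem, 0 passed camera, with a smallest adjusted p of 0.452 and 3 at an unadjusted p under 0.05 (SNX, ZNF and RPL). The 2576 probes with a value on 1 array only had a median log2 ratio of 0.44, and 23.0% of them were at or above 1, against 1.49% and 1.60% of probes on both arrays. Among probes unnamed here, 18 were 2-fold higher and 6 lower on both arrays.

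Genes of cell types absent from HepG2 cultures stand among the highest ratios. A shift of all dim probes by the dyes by 0.5 or more is argued against by the 86 olfactory receptor genes, assumed here to be dim. Their median of -0.10 (95% interval -0.18 to 0.01) lay under that bar, set beforehand. The probes with a value on 1 array only, for which no bar was set beforehand, had a median of 0.44 (95% interval 0.40 to 0.48). That interval lies above 0, so these probes do not argue against an upward shift, and whether they are dim is unknown. For independent noise on each array, the test written beforehand counted 2 of 112 receptor and marker genes at or above 1 on both arrays, against a mean of 0.267 over 10000 random pairings (one-sided permutation p = 0.0230), which by its own terms went against noise. Its 2 genes were OR1S1 and OR5AS1, the receptors that had prompted the pattern, with 0 others, so the test was set aside as circular and replaced, after its outcome was known, by correlations without them. Across 84 genes, which are not independent replicates, the Spearman correlation was 0.198 (two-sided permutation p = 0.0702, adjusted over both correlations 0.0702) and the Pearson correlation 0.287 (p = 0.00880, adjusted 0.0176), so the latter goes against fully independent noise and the former misses the threshold, and noise in the leading genes themselves stays open without intensities.

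The acute-phase list lies higher in cytokine-treated cells. One experiment alone is argued against, since the list's median lay at or above the 99.97th percentile of random lists on each array. Whether an upward effect was shared by liver transcripts in general could not be decided from the 25 hepatocyte identity genes. Their median was -0.12 (95% interval -0.36 to 0.02), against the acute-phase median of 0.46. On the 2 arrays their medians were -0.183 and -0.135, against 0.631 and 0.257, with 11 of these genes lower and 5 higher on both. The gap between the medians was larger than the SD of the hepatocyte identity genes on replicate 1 (0.81 against 0.53) but not on replicate 2 (0.39 against 0.58). The bar asked for a larger gap on each array, so it was not met. The hepatocyte identity genes may themselves respond to the cytokines, and a fall of theirs could hide a shared rise. An effect shared by all or only some liver transcripts therefore stays open. With 0 dye-swapped arrays, a dye effect of these probes and the cytokines cannot be told apart. A response of these genes to IL-17A and IL-22 remains a hypothesis beside that.

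The cell cycle list lies lower in cytokine-treated cells. One experiment alone is argued against by the list's median, at the 0.35th percentile of random lists or lower on each array, and the choice of members by the mitosis list, whose median lay at the 0.25th percentile. By the latter measure, on the mean of the arrays, the median of the 86 olfactory receptor genes, assumed to be dim, lay at the 0.05th percentile. So low a percentile is therefore not particular to genes of dividing cells. A shift shared in equal size with the pooled lists of reference genes and of glycolysis and hypoxia genes is argued against by the difference from them, -0.14 (95% interval -0.23 to -0.05). That interval takes genes as independent and holds no spread between the experiments. Medians on the 2 arrays were -0.24 and -0.16 for cell cycle genes, -0.15 and -0.09 for reference genes, and -0.08 and -0.01 for glycolysis and hypoxia genes. Ribosomal proteins also lay lower, and the difference from them was -0.069 (95% interval -0.18 to 0.09), so a shift shared with these genes stays open. A dye effect of these probes and an effect of the cytokines were not tested apart and stay open too.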
